A study of Mus musculus with 2 samples.

How the data were processed

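Poly-A RNA of mouse primary hepatocytes, liver cells taken from the animal and kept in culture, was sequenced after transfection with 1 of 2 small interfering RNAs. One library came from cells given siRNA against ClpP, the protease subunit of the mitochondrial matrix ClpXP complex, and the other from cells given siRNA against green fluorescent protein (GFP), the control. Each group held 1 library. Per the labels' protocols, the libraries were made with the Illumina TruSeq RNA kit v2, and per the series' design text the siRNA was delivered with Lipofectamine, a cationic lipid reagent. The animals, the dose of siRNA and the time of harvest were not given in the sources used here.

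Expression came from 1 deposited table with a row per gene, keyed by NCBI gene ID and RefSeq transcripts. Per the file headers, 2 columns hold FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) as computed by the authors. Per the submitters' processing notes, the tools were FastQC 0.10.0, Trimmomatic 0.32, TopHat2 2.0.13, Bowtie2 2.2.3, Cufflinks 2.2.1 and STAR 2.4.0f1. The notes as used here give neither the role nor the order of these tools, and the genome build was not given in the sources used here, so no coordinates are printed. The table also holds 2 columns of log2 values deposited by the authors, 1 per library. Recomputing log2(FPKM + 1) with quantile normalization of both libraries gave those log2 values to within 0.001. A last column, treated here as a score, is the authors' deposited signed fold change, which equals 2 to the power of the difference of the log2 columns, to within 1e-06, written as a negative inverse where the ClpP siRNA library was lower. One library is named GFP in the column headers. The other header is an abbreviation that was read as ClpP siRNA from its name alone, and no value was used for that reading.

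The table had 14346 rows, all above 0 in both libraries, so a gene at 0 in either library was not analysed here, and a gene switched fully on or off could not be seen. Of these rows, 7 named no gene and were left out; they held 0.0475% of the FPKM total in the GFP siRNA library and 0.0335% in the ClpP siRNA library. The other 14339 rows each named a different gene. The FPKM totals were 532555 and 535315 in the GFP siRNA and ClpP siRNA libraries. FPKM carries no read count, and the low values (37 and 57 rows below 0.001) are model estimates rather than steps of whole reads. The depth of either library is therefore unknown, and no counting interval or detection floor is given.

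The measure was the log2 ratio, log2(FPKM + 1) in the ClpP siRNA library minus log2(FPKM + 1) in the GFP siRNA library, which understates the change of genes of low FPKM. Genes with a mean FPKM over both libraries of at least 1 were kept, 11087 in all. With 1 library per group there is no replicate check, no test, no p-value and no standard error. A gene is counted as higher or lower where its log2 ratio was at least 1 in size (2-fold), a rule of size that says nothing about chance. As a description of scatter, a gene was set beside the 500 genes nearest in mean FPKM. The 16th and 84th percentiles of their log2 ratios are called the local spread, which mixes technical scatter with real differences. The text prints this spread for Clpp only.

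Gene lists (49, of pathways, complexes and cell type markers) and the rule for the genes named were set before the data were examined. For each list with at least 5 members passing the filter, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean FPKM. A list is said to stand apart where its median lay outside the central 95% of the random medians. This describes these 2 libraries and is not a test of the siRNA. The text names Clpp, the 12 genes with the highest and the 12 with the lowest log2 ratio, and up to 4 members of each list with the largest ratios in size. For the highest and lowest genes the higher FPKM had to be at least 5, and predicted gene models, small RNA genes and pseudogenes were left out. The most abundant members were named as well for the cell type markers and the liver identity list. Some members that this rule selects are not reported here. Any other gene is named as chosen after its values were seen. Genes with near-identical copies (the Ifit3, Gsta, Gstm, Saa, Serpina1, Mup, Ces3, Apol9, Phf11 and H2 families, and ribosomal proteins with retrocopies) can exchange reads, so the value of a single member is uncertain.

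The procedure was tested on simulated data for the comparison of ClpP siRNA with GFP siRNA, over 11087 genes with the observed scatter and known changes placed on the FPKM. The size rule found 32% of genes made 2-fold higher and 29.8% of those made 2-fold lower, since scatter puts a change of that size on either side of the limit and the added 1 shrinks it. It found 98.0% and 93.5% of those made 4-fold higher and lower, and 1.18% of the unchanged genes. Of 200 unchanged lists of 30 genes, 3% stood apart, and so did 100% of 100 lists with 0.5 added to their log2 ratios. Both outcomes were largely set by the construction, since unchanged lists and random lists were drawn from nearly the same genes. They check the computation and do not show how real lists behave. The simulated scatter was drawn for each gene separately, unlike that of real lists whose members can shift together. It also leaves out any wider tails of the real scatter, so the 1.18% is no error rate for the observed counts.

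The gene counts, the medians of the lists set beforehand and the ratios of the genes named by the rule, Clpp among them, were recomputed under other settings. These were other pseudocounts (0.1 and 5), filters (none, and a mean FPKM of at least 5) and scalings (median, upper quartile, quantile normalization, and totals without the 50 most abundant genes). The same results were recomputed without predicted gene models and on the log2 values deposited by the authors. Lists written after the values were seen were not recomputed. Counts were repeated at 1.5-fold and 3-fold, and lists with 5 bins, no matching and the mean in place of the median. Leaving the interferon genes out of the counts and of other lists was chosen after the data were seen. No scaling moved the median log2 ratio of all genes by over 0.1. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Transcript lengths came from GENCODE M21 through RefSeq transcripts and were used only in the closing section.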

Results

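Gene expression was compared between primary mouse hepatocytes given ClpP siRNA and hepatocytes given GFP siRNA, to see which genes change in expression when ClpP is targeted. There was 1 library per group and no replicate, so each difference is between 2 libraries, and its size can be set only beside the scatter of other genes. FPKM was measurable in both libraries for 14339 named genes, and 11087 had a mean of at least 1. The 50 most abundant genes held 27.2% of the FPKM total in the GFP siRNA library and 25.6% in the ClpP siRNA library. Across genes, which are not independent replicates, log2(FPKM + 1) in the 2 libraries had a Pearson r of 0.942.

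Clpp (NCBI gene 53895), the targeted gene, had an FPKM of 45.1 in the GFP siRNA library and 9.32 in the ClpP siRNA library. Its log2 ratio was -2.16, beyond the local spread of -0.29 to 0.37, and the authors' deposited table gives a fold change of -4.62. Among the 11087 genes, 575 were at least 2-fold higher in the ClpP siRNA library and 226 at least 2-fold lower, so that 71.8% of the genes past 2-fold were higher. At 8-fold the counts were 65 and 3. The median log2 ratio of all genes was -0.01, with 16th and 84th percentiles of -0.36 and 0.40.

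Most of the 12 highest log2 ratios among named genes belonged to antiviral and immune genes. Ifit3 (NCBI gene 15959), an interferon-induced protein that binds viral RNA complexes, stood at 5.28 FPKM with GFP siRNA and 1078 with ClpP siRNA, a log2 ratio of 7.42. Ly6a, an interferon-inducible surface protein, followed at 6.95 (4.22 to 644 FPKM), and Ccl5, a chemokine that draws T cells and monocytes, at 6.88 (17.4 to 2166 FPKM). Oas3 (6.15) and Rsad2 (5.97), enzymes of the antiviral response, and Mx1 (5.69), an antiviral GTPase, came next. The list went on with Mnda (5.45), Ifi204 (4.91) and Ifi205 (4.59), which belong to a family of interferon-inducible nuclear proteins, and with Phf11d (5.21), Phf11b (4.94) and Ifit2 (4.84). Of these 12 genes, 7 belong to the interferon response list, as do 25 of the 50 genes with the highest ratios when predicted gene models are included.

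The lowest log2 ratio was that of S100g (NCBI gene 12309), a calcium-binding protein, at -4.25 (55.2 to 1.95 FPKM). Hsd17b13, a lipid droplet enzyme of hepatocytes, had a ratio of -3.18 (271 to 29.1 FPKM), and Ahsg, the secreted plasma protein fetuin-A, -3.11 (2267 to 261 FPKM). Marcksl1 (-2.95) and Dbn1 (-2.58), which bind actin or act on it, and Ddah2 (-2.81), which takes part in methylarginine metabolism, were also among the lowest. Gsta1 (-2.71) and Gsta2 (-2.70) encode glutathione transferases and share much of their sequence. Ftcd (-2.59) encodes an enzyme of histidine breakdown. Esm1 (-2.49), a secreted proteoglycan of endothelial cells, Tead2 (-2.47), a transcription factor of the Hippo pathway, and Mest (-2.45), an imprinted gene, complete the 12.

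**Figure D1:**
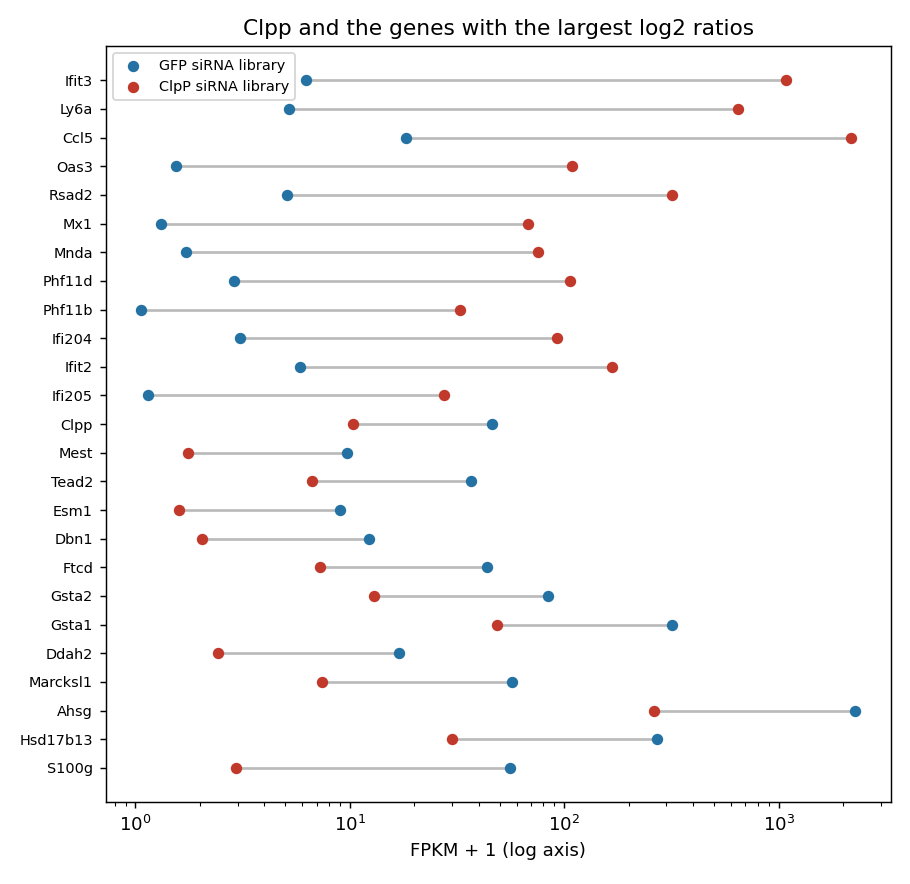
FPKM + 1 on a log axis in the GFP siRNA library (blue points) and the ClpP siRNA library (red points) for Clpp and the 12 genes with the highest and 12 with the lowest log2 ratio, 1 library each. Ifit3 lies at 5.28 FPKM in the GFP siRNA library and 1078 in the ClpP siRNA library, and Clpp at 45.1 and 9.32.

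The interferon response list was higher as a whole. All 58 members passed the filter and lay above 0, 56 of them were at least 2-fold higher, and the median log2 ratio was 2.99, above all 10000 random lists. The smallest ratios were those of Irf9 (0.89) and Ifi27l2a (0.78), named after their values were seen. I830012O16Rik, a near-identical copy of Ifit3 whose reads cannot be separated from it with certainty, had a ratio of 7.22. The list accounts for 29 of the 65 genes past 8-fold, and leaving it out, 519 genes were still at least 2-fold higher. A list of 58 genes can hold only a small part of 575, and interferon-inducible genes outside it, such as Ly6a, were among the highest. How many of the other genes belong to the interferon response cannot be read from this count. The median of the macrophage markers in the same comparison was -0.67 and that of the hepatocyte markers 1.08.

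**Figure D2:**
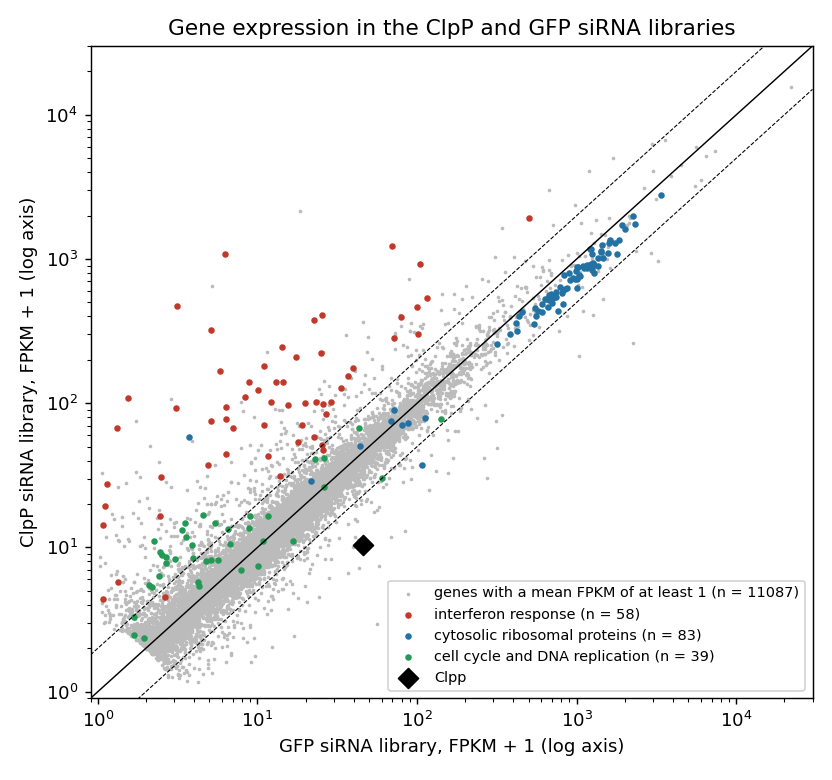
FPKM + 1 of each gene in the ClpP siRNA library against the GFP siRNA library, both on log axes, with equal values on the solid line and 2-fold differences of FPKM + 1 on the dashed lines (11087 genes, 1 library per group). The 58 interferon response genes (red) lie above the solid line, 78 of the 83 cytosolic ribosomal protein genes (blue) lie below it, 34 of the 39 cell cycle genes (green) lie above it, and Clpp (black diamond) lies below the lower dashed line.

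Other immune lists moved less. The proteasome list had a median of 0.22 (37 members, percentile 99.84), and its 3 members past 2-fold were the immunoproteasome subunits Psmb9 (2.34), Psmb8 (1.98) and Psmb10 (1.73); the next largest, Psma1, had 0.44. Leaving out the interferon genes gave a median of 0.19 (percentile 99.20), while with the mean in place of the median the list no longer stood apart. Acute phase genes, which hepatocytes secrete in inflammation, had a median of 0.42 (31 members, 9 higher and 4 lower past 2-fold, percentile 99.99), and their mean did not stand apart. Members went far in both directions. The serum amyloids Saa2 and Saa1 had ratios of 3.69 and 3.06, while Crp had -1.99 and haptoglobin (Hp) -1.73, from 3213 to 969 FPKM. Inflammatory cytokines and NF-kB targets did not stand apart (median 0.06, 26 members), with 5 higher and 2 lower past 2-fold. Ccl5 led them, followed by Il33 (1.84), Ccl7 (1.43) and Tlr2 (1.38). The list of siRNA and double-stranded RNA machinery had a median of -0.01 over 14 members, of which 4 were higher: the sensor Tlr3 (2.58), the RNA editing enzyme Adar (1.35), Eif2ak2 (1.17) and Zc3hav1 (1.02), the last of which fell short of 2-fold under 3 of the other scalings.

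Markers of cell types moved apart. Of 7 hepatocyte markers, 5 were higher past 2-fold, with a median of 1.08 (percentile 99.90). Cps1, the first enzyme of the urea cycle, had 2.79 (3.15 to 27.8 FPKM), Apoa1 1.75, Ttr 1.08 and albumin (Alb) 1.08 (2952 to 6245 FPKM). Lower values were those of Apob at -0.32 and of Asgr1, named after its values were seen, at -0.61. Ttr fell short of 2-fold after quantile normalization. Tat, also counted as higher and named after its values were seen, was close to the limit at 1.01. Its ratio was not recomputed under the other settings. Macrophage markers had a median of -0.67 over 6 members (percentile 0.10), with Lyz2 at -0.97, Cd5l at -0.89, C1qa at -0.76 and C1qc at -0.58, all below 4 FPKM. Cd68, a lysosomal protein, went the other way at 3.14 (24.9 to 226 FPKM), and with it the mean of the list was -0.08 and did not stand apart. Sinusoidal endothelial markers had a median of -0.48 over 7 members (percentile 0.58), with Pecam1 at -1.36 and Cdh5 at -1.20, then Eng at -0.79, Fcgr2b at -0.48 and Oit3 at 0.33. Of the stellate cell and fibroblast markers only 4 passed the filter (median -0.48): Acta2 at -1.39, Col3a1 at -0.95, Col1a1 at 0.01 and Dcn at 0.00. Cholangiocyte markers had a median of 0.14 over 5 members and did not stand apart, with Krt19 at 2.27, Spp1 at -0.88 and Sox9 at 0.14. None of the 12 lymphocyte markers was listed above 0 in both libraries, and no neutrophil or erythroid marker passed the filter.

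Genes of hepatocyte function went both ways. The list of liver transcription factors and secreted proteins had a median of 0.05 over 41 members and did not stand apart, with 9 higher and 4 lower past 2-fold. Beside Ahsg, Serpina1b (-1.64), an antitrypsin gene with near-identical copies, was lower, and Serpina3k (2.19) and antithrombin (Serpinc1, 1.95) were higher. Among its most abundant members, Gc had -0.32 (6417 to 5155 FPKM), transferrin (Trf) -0.76 and hemopexin (Hpx) 0.09. Lipoprotein genes stood apart upwards with a median of 0.68 (19 members, 8 higher and 0 lower past 2-fold), above all 10000 random lists. Apoa2 had 2.99 (45.1 to 367 FPKM), Apoa5 2.78, Gm6484, which encodes Angptl8, 2.05 and Apoc3 1.95. Genes of the urea cycle and amino acid breakdown had a median of 0.26 (32 members, 8 higher and 1 lower, percentile 99.94), led by Cps1, Hal (1.54), Hgd (1.37) and Mat1a (1.19). Drug and steroid metabolism (median 0.08, 34 members) did not stand apart but had 5 higher and 4 lower past 2-fold. The carboxylesterases Ces3b (2.80), Ces3a (2.23) and Ces2a (1.71) were higher and Cyp2a5 (-1.67) was lower. Bile acid synthesis and transport had a median of 0.02 over 16 members, whose sign depends on the filter, with the transporters Abcc4 (-1.74) and Abcb4 (-1.30) lower, and Slc27a5 at 0.83 and Cyp7b1 at -0.63.

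The lists of genes of the mitochondrion, where ClpP acts, differed little in their medians. Mitochondrial genes placed in other lists are not covered by this. Of 26 mitochondrial proteases and chaperones, 0 were past 2-fold and the median was -0.03. The largest ratios were those of Lonp1 (-0.79), the other main matrix protease, Yme1l1 (-0.33), Lactb (0.32) and the chaperone Hspa9 (-0.31). Clpx, the partner of ClpP, and Hspd1, a chaperone often read as a marker of mitochondrial protein stress, had 0.16 and -0.23 and were named after their values were seen. Nuclear genes of complex I (median -0.03, 36 members) and of complexes II to V (-0.06, 41 members) had 0 members past 2-fold and did not stand apart. Their largest ratios were those of Ndufa4 (-0.50), Ndufa11 (0.49), Cox7c (-0.56) and Cox8a (-0.44). Genes of the mitochondrial genome were not analysed here. Mitochondrial ribosomal proteins had a median of 0.12 over 76 members (percentile 99.06), with 0 past 2-fold, and their mean of 0.08 did not stand apart. Mrpl30 (0.67), Mrpl46 (0.66), Mrpl34 (-0.61) and Mrpl27 (0.59) had the largest ratios.

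The other mitochondrial lists did not stand apart. Mitochondrial translation factors had a median of 0.05 (24 members), with Noa1 at -0.61 and Nsun4 at 0.59. Protein import had -0.09 (26 members), and its 1 member past 2-fold was Timm21 (-1.43, 14.1 to 4.62 FPKM), a subunit of the inner membrane translocase. Biogenesis and DNA maintenance had -0.12 (17 members), with Tfb2m at -0.80 and Ssbp1 at -0.74. Dynamics and mitophagy had 0.01 (15 members), with Mtfp1 at 0.49. In the tricarboxylic acid cycle (median 0.04, 23 members) Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, stood alone past 2-fold at -1.22 (82.2 to 34.6 FPKM). Fatty acid oxidation and ketogenesis had a median of -0.04 over 29 members with 0 past 2-fold.

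Of the lists of stress responses, 3 were lower and 3 did not stand apart. The integrated stress response list, targets of the transcription factors ATF4 and CHOP, had a median of -0.44 (36 members, 31 below 0), below all 10000 random lists, with 9 lower and 2 higher past 2-fold. Phgdh (-1.61), the first enzyme of serine synthesis, Atf5 (-1.59), a transcription factor of the mitochondrial stress response, and Aldh18a1 (-1.42), of proline synthesis, were lower. Ddit3, which encodes CHOP itself, was higher at 1.56 (36.1 to 109 FPKM). Atf4 had -0.75 and Asns -1.37, both named after their values were seen. NRF2 target genes had a median of -0.21 (37 members, 9 lower and 1 higher past 2-fold, percentile 0.84). The lowest were Gsta1, Gsta2, Gstm3 (-2.28) and Gstm1 (-2.27, 1025 to 212 FPKM), all glutathione transferases, and the list did not stand apart after quantile normalization. p53 targets and apoptosis genes had a median of -0.17 (31 members, percentile 1.62) with 0 past 2-fold, a call lost under 4 other settings. Bbc3 had -0.98 and Pmaip1 -0.92, both inducers of apoptosis, and Bbc3 passed 2-fold under some scalings. The unfolded protein response of the endoplasmic reticulum (median 0.11, 29 members), cytosolic heat shock (0.20, 16 members) and the hypoxia response (0.10, 21 members) did not stand apart. Their largest ratios were those of Wfs1 (0.93), the small heat shock protein Hspb1 (1.29, 704 to 1718 FPKM) and Ldha (0.77).

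**Figure D3:**
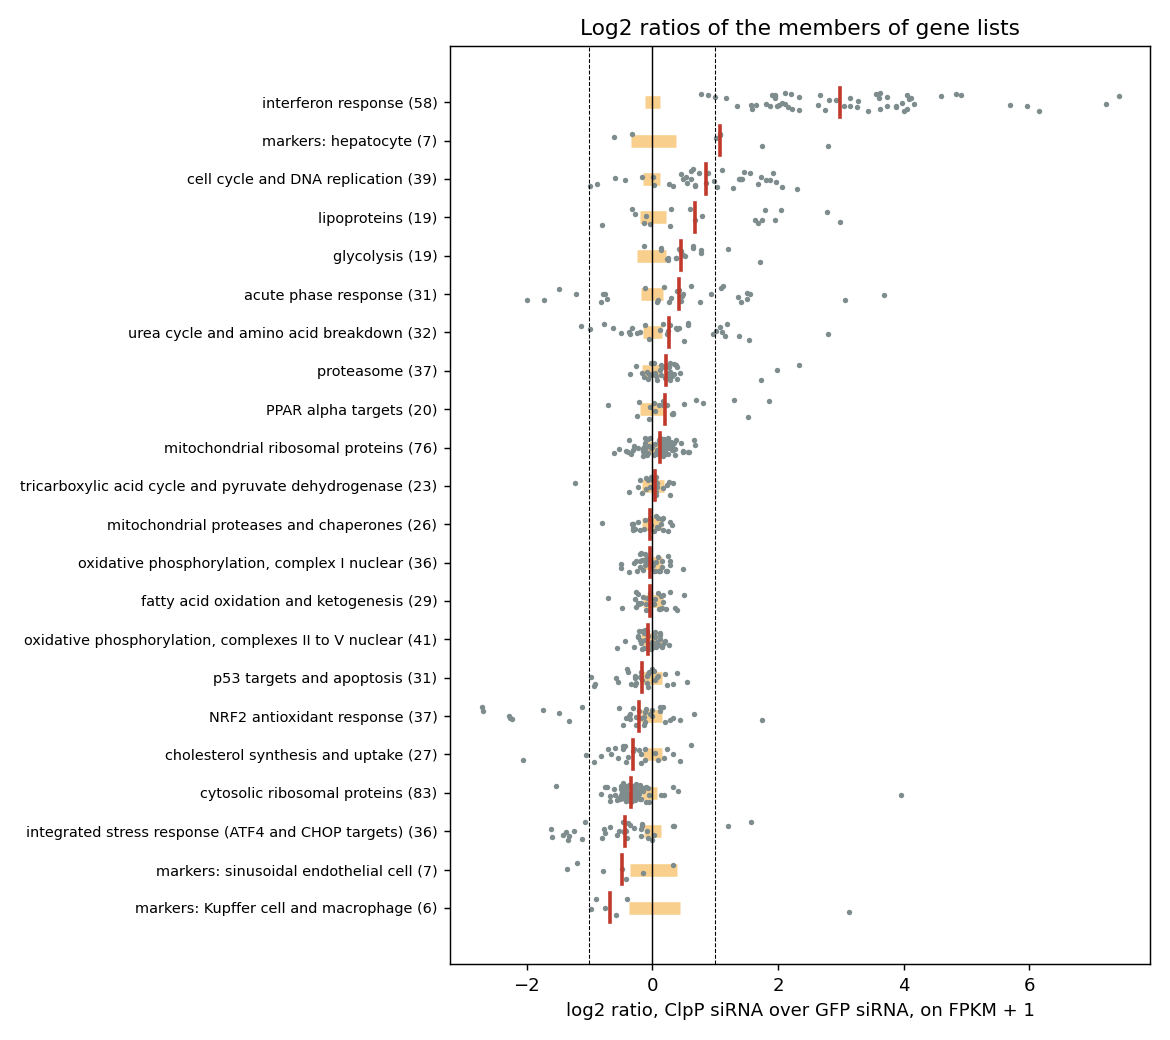
Log2 ratio on FPKM + 1, ClpP siRNA over GFP siRNA, of each member (grey points) of the lists that stood apart and of 5 mitochondrial lists that did not, with the number of members in brackets. Red bars are list medians, orange bars span the central 95% of medians of 10000 matched random lists, and dashed lines mark 2-fold; the interferon median lies at 2.99 and that of the proteases and chaperones at -0.03.

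Metabolic lists outside the mitochondrion differed in both directions. Glycolysis genes had a median of 0.46 (19 members, 18 above 0, percentile 99.97), with Pkm (1.71, 71.9 to 238 FPKM), the pyruvate kinase that is scarce in adult liver, and Hk1 (1.21) past 2-fold, and Slc16a1 at 0.78. Cholesterol synthesis and uptake had a median of -0.30 (27 members, 20 below 0, percentile 0.01), with Tm7sf2 (-2.05) and Hmgcs1 (-1.06) lower past 2-fold and Idi1 at -0.93. PPAR alpha targets had a median of 0.20 (20 members, percentile 97.75), close to the limit and within it with a pseudocount of 5, and 3 were higher: Txnip (1.86), Vnn1 (1.52) and Angptl4 (1.30). Fatty acid and triglyceride synthesis (median -0.06, 29 members) did not stand apart, although Thrsp, a lipogenic nuclear protein, had 3.44 (7.07 to 86.8 FPKM) and the desaturases Scd1 (-1.63), Scd2 (-1.55) and Fads1 (-1.03) were lower. Gluconeogenesis and glycogen genes (median 0.01, 21 members) did not stand apart, with Igfbp1 at -1.99.

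Cell cycle and DNA replication genes stood apart upwards with a median of 0.85 (39 members, 34 above 0), above all 10000 random lists, and 17 were at least 2-fold higher with 0 lower. The largest ratios were those of Ccnb2 at 2.30 (1.26 to 10.1 FPKM), Birc5 at 2.06, the thymidine kinase Tk1 at 1.97 and Plk1 at 1.92, all at low levels. Cytosolic ribosomal protein genes had a median of -0.35, below all 10000 random lists, and 78 of 83 were below 0, though only Rpl22l1 (-1.53) was past 2-fold lower. Rpl3 had -0.81 and Rpl10a -0.75. Rps27 had 3.96 (2.75 to 57.2 FPKM), while its near-identical retrocopy Rps27rt, named after its values were seen, had -0.76 (1076 to 633 FPKM), so that reads assigned between the copies make the ratio of Rps27 uncertain.

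The remaining lists did not stand apart. Immediate early genes had a median of -0.07 (23 members), with Egr1 at -1.32 and Ier2 at -1.03. Extracellular matrix, cytoskeleton and dedifferentiation genes had -0.07 (42 members, 4 higher and 4 lower), with Myl9 at -1.96. Autophagy and lysosome genes had 0.05 (39 members) with 4 higher past 2-fold, among them Npc2 (1.62), Ctsb (1.46, 190 to 524 FPKM) and Gla (1.12). Iron and heme genes had -0.01 (32 members), and hepcidin (Hamp) was the 1 member past 2-fold at 1.37 (401 to 1038 FPKM). Growth factors and hepatokines had 0.06 (24 members), with Igfbp2 at 2.70 and Igfbp4 at -2.24. Clock genes had 0.12 (17 members) and 0 past 2-fold. The list of sex-linked and donor genes had -0.09 (11 members), with Mup11 at 1.87 and Mup17 at -1.23, whose family shares reads. It was written to join genes of either sex, so its median cannot show whether the donors differed. Some named genes near 2-fold depended on the pseudocount. With 5 in place of 1, Pecam1, Cdh5, Aldh18a1, Timm21, Scd2, Fads1, Hmgcs1, Hk1, Hal, Hgd, Eif2ak2, Zc3hav1, Gla, Ier2 and Mup17 fell short of it, and with 0.1 Lyz2, Cd5l, C1qa, Col3a1, Slc27a5, Bbc3 and Pmaip1 passed it. Over all lists, 44 could be placed among random lists, and 10 stood apart upwards and 7 downwards, against 2.2 in all if lists behaved like random ones. The 2.2 is no measure of chance here, because members of a real list can shift together and some lists share members.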

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

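Clpp, the gene counts and the lists set beforehand were recomputed under the alternatives described above, and 583 of those values were labelled the same. That label means the same side of 2-fold for Clpp, within 1.5-fold of the main value for a gene count, and the same call for a list. Otherwise 8 gene counts moved, and among list medians 11 calls were lost, 4 were gained and 1 median reversed. The lists written after the values were seen were not recomputed. The Clpp ratio ranged from -2.26 to -1.81 and the interferon median from 2.29 to 3.25. Genes higher numbered 327 with a pseudocount of 5, 1105 at 1.5-fold and 270 at 3-fold. Genes lower numbered 357 with a pseudocount of 0.1, 89 with 5, 142 with a mean FPKM of at least 5, 753 at 1.5-fold and 61 at 3-fold. These follow from the construction of the settings. The share of higher genes among those past 2-fold stayed between 67.2% and 78.6% over pseudocounts, filters and scalings. With the mean in place of the median, the macrophage (-0.079, set by Cd68), mitochondrial ribosomal (0.082), acute phase (0.39) and proteasome (0.30) lists no longer stood apart, while the NF-kB (0.37, with Ccl5) and immediate early (-0.21) lists did. With no filter the immediate early (-0.18) and bile acid (0.16) lists stood apart, the latter upwards. With a mean of at least 5 the bile acid median reversed to -0.24 and stood apart downwards (percentile 2.24), as other members were counted. PPAR alpha targets no longer stood apart with a pseudocount of 5 (0.12). The same held for NRF2 targets after quantile normalization (-0.22) and on the deposited log2 values (-0.22). It held for p53 targets with a pseudocount of 5 (-0.075), a mean of at least 5 (-0.13), upper quartile scaling (-0.20) and totals without the 50 most abundant genes (-0.19). Where no cause is given, the cause was not tested. Of the ratios of 197 named genes, 1896 alternatives kept their side of 2-fold, 22 passed it, 23 fell short and 0 reversed. With a mean of at least 5, the macrophage, endothelial and cholangiocyte lists had too few members. Using read counts was not run, since the table holds none, and keeping 1 row per gene name changes nothing, as each name has 1 row. No paired analysis was possible because each group has 1 library. The unknown depth most limits genes near 1 FPKM, among them the macrophage and cell cycle genes.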

Other observations

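The lists in this and the next paragraph were written after the values were seen. Those of the Schlafen and Phf11 families, of glutathione transferases and of YAP and TEAD targets were prompted by genes among the highest or lowest. The counts and medians of all these lists are no independent evidence. Genes of antigen presentation by MHC class I were higher together, but they include Tap1 of the interferon response list and so partly recount that result. Of 21 members passing the filter, 21 were above 0 and 15 at least 2-fold higher, with a median of 1.63. H2-K1 went from 1681 to 5039.7 FPKM and H2-D1 from 1184 to 4056, and the peptide transporter Tap1 had 2.12 and Tap2 1.82, though H2 genes share reads. All 8 members of the Schlafen and Phf11 families were at least 2-fold higher (median 3.34), among them Slfn5 (3.52) and Slfn2 (3.16). Interferon receptors, ligands and signalling genes differed less, with a median of 0.24 over 15 members. In that list Trex1 (2.83), Irf5 (2.11) and Socs1 (1.17) were past 2-fold, while Ifnar1 (-0.41), Irf3 (-0.39) and Ifngr1 (-0.31) were slightly lower. Complement and coagulation genes had a median of 0.39 over 35 members, with 9 higher and 0 lower past 2-fold, among them F11 (2.19), C8g (2.15) and C2 (1.81, 88.8 to 314 FPKM).

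Glutathione transferases as a class had a median of -0.42 over 21 members, with 8 lower past 2-fold and 1 higher, Gstt3 (1.08). Gsta3 (-2.24) was low beside Gsta1 and Gstm1. NRF2 targets outside this class differed among themselves, with Abcc4 (-1.74), Slc7a11 (-1.33) and Cbr3 (-1.12) past 2-fold lower, G6pdx higher at 1.74, and Nqo1 (-0.53), Hmox1 (0.17) and Srxn1 (0.00) within 2-fold. Genes of the contractile cytoskeleton and targets of YAP and TEAD had a median of -0.46 over 22 members, with 8 lower and 1 higher, Ankrd1 (1.60). Wnt targets of the pericentral liver (median 0.29 over 7 members) did not stand apart.

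Of the tests in the 3 paragraphs that follow, those on macrophage RNA, on siRNA transfection, on the share of hepatocytes and on scaling were chosen after the results were seen. The list of leukocyte genes was written after the values of other genes were seen, but before its own result.

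The interferon response genes were higher in the ClpP siRNA library by a median of 2.99. RNA from macrophages would bring its abundant transcripts along, yet the median of 6 markers was -0.67, with Lyz2 at 1.30 and Cd5l at 1.68 FPKM in the ClpP siRNA library; Cd68, which other cells express too, is the exception at 3.14. RNA from leukocytes in general is also argued against by a median of -0.28 over 5 leukocyte genes, and of -0.63 over 4 without Lcp1, whose 94.1 FPKM with GFP siRNA would hide a small share, although Plac8 had 0.84 and genes at 0 in either library are not seen. Unequal transfection, or a sequence of the siRNA that itself triggers RNA sensing, cannot be told apart from an effect of losing ClpP. The 7 sensors looked at had a median of 2.58, but they are interferon-induced themselves, and there was 1 siRNA per group; a biological effect of ClpP loss may equally account for the pattern and was not tested.

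Hepatocyte genes moved both ways, with 9 of the liver identity genes higher and 4 lower past 2-fold. A smaller share of hepatocytes in the culture, as the cause for the lower genes, would raise the markers of the cells taking their place. The 13 macrophage and endothelial markers had a median of -0.58, with 11 below 0, which argues against a larger share of macrophages or endothelial cells. It does not cover other cell types. The cholangiocyte markers had a median of 0.14, with 4 above 0 and 1 below. The 4 stellate cell and fibroblast markers passing the filter had a median of -0.48, with 1 above 0 and 3 below. They were too few to be placed among random lists. Different scaling of the libraries moves all genes the same way, so it could not give changes in both directions whatever the factor. Over 3 scalings the largest factor between the libraries was 1.04, far from the 2-fold changes counted in either direction. A larger share of hepatocytes stays open for the genes that were higher. The medians of macrophage and endothelial markers lay on the side it needs, as did that of the hepatocyte markers (1.08). The hepatocyte markers share Alb, Ttr and Asgr1 with the liver identity genes, so their median partly restates the pattern. Apob (-0.32), Asgr1 (-0.61), Cd68 (3.14) and the cholangiocyte markers (median 0.14) did not lie on that side. A median of 0.053 over the 41 liver identity genes, with members going both ways, does not decide it. An effect of the ClpP siRNA on separate groups of secreted proteins, and a difference between cultures or in their inflammatory state, also stay open and could not be tested with 1 library per group.

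Ribosomal protein genes were lower by a small and even amount, with 78 of 83 below 0. Transcript length does not account for it. Among 10000 lists matched on length and mean FPKM the percentile was 0, with lengths known for all 83 genes, and complex I genes of like length (medians of 745 and 799 bases) had a median ratio of -0.03. The 50 most abundant genes of each library held 27.2% of the FPKM total with GFP siRNA and 25.6% with ClpP siRNA. A difference in share of that size is too small to account for the lower median. Leaving the 50 most abundant genes out of the totals gave a factor between the libraries of 1.03 and a median of -0.39. A factor that small could not have brought the median near 0, so the recomputed median is no separate evidence. The genes left out may include ribosomal protein genes. A lower level of these transcripts in the ClpP siRNA library is a candidate explanation and remains a hypothesis from the same 2 libraries, and whether it follows from ClpP, from the interferon response or from the cultures was not tested.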
